A study of Homo sapiens with 16 samples.

How the data were processed

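The deposited files were 13 peak lists in BED form, 1 per chromatin immunoprecipitation library: BMAL1 at 6 times in U2OS, BMAL1 at 6 times in U2OS-CHRONO, and Myc in U2OS-CHRONO. The 3 input libraries of the series had no list and were not analysed here. Per the labels, chromatin was cross-linked with formaldehyde and sonicated, and the libraries were sequenced as DNA nanoballs. The submitters' processing notes name MACS 1.4.2, bedtools, HOMER 4.10.3 and the build hg38, without saying what each did. The aligner, the read depth and the control used for calling are not given in the sources used here. Each list holds the chromosome, start, end and a score per peak. The score is the authors' own value, as deposited, and its definition is not stated; MACS of that version writes -10 times the log10 of a p-value there by convention, and the lowest score of all lists was 50. The score was used only to rank or filter peaks within a list. Since each library had its own list, peaks were taken as called per library.

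Depth is not known, so a longer list can come from deeper sequencing or better enrichment as well as from more binding. List length was therefore varied in an alternative with as many top-scoring peaks in both lines at each time. Wilson 95% intervals of shares of peaks cover counting error only.

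Protein-coding genes with a place on a chromosome (20037) came from the RefSeq gene table of GRCh38, the same assembly as hg38. The table gives no strand, so the planned window around the transcription start was replaced by 1 kb either side of both ends of a gene, called a gene end here. Exon and intron positions were not used here. The planned share of peaks with a CACGTG motif was not run, since it needs a genome sequence. All 239 symbols of the 10 gene lists were found in the table.

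Peaks overlapped when they shared at least 1 bp. Merged regions joined overlapping peaks of the 12 BMAL1 libraries. A region was gained in U2OS-CHRONO with a peak at 4 or more additional times there, and lost with 4 or more additional times in U2OS. Lines were compared by two-sided exact paired sign-flip permutation tests over the 6 times, with Benjamini-Hochberg adjustment over 4 tests (peak number, gene-end share, core clock genes, share of Myc peaks) and, separately, over the 10 lists. The time profiles were compared by Pearson's r and Spearman's rho with exact permutation of the pairings, and the Jaccard index of matched times by exact permutation of the time labels. Gene lists were tested by Fisher's exact test against all other protein-coding genes per list and library, adjusted over 130 tests. Myc peaks were compared with 100 random placements on the same sequences, of the length reached by the peaks and genes seen on each.

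The tests, lists and alternatives were fixed before the data were examined, except the gene-end window and the sets of tests over which the paired p-values were adjusted. The pairs come from the time labels. Genes were named by a rule fixed then: all core clock genes, up to 4 members of each other list with a gene-end peak in the most BMAL1 libraries, the 10 genes with such a peak in the most BMAL1 libraries with ties broken by mean score percentile, the 10 largest differences in number of times in each direction with ties broken in the same way, and the 10 with the highest Myc score. Of the genes so named, 2 are not reported here. Alternatives were a score of at least 100, equal list sizes, chromosomes 1 to 22 and X alone, an overlap of 50% of the shorter peak or centres within 500 bp, a 5 kb window, no pairing, a difference of 3 times, BMAL1 at 4 or more times, and each time left out. A window of the gene with 5 kb to each side, and the alternatives of the list enrichment other than the 5 kb window, were added after seeing the data. Simulated lists had 200 of 20968 regions changed, each with a peak at every U2OS-CHRONO time and at no U2OS time. That is the largest change possible, so the recovery of 100% of them as gained was fixed by construction. Sensitivity to smaller changes or missed peaks was not tested. In the same lists 93 and 76 unchanged regions were called gained and lost. Overlap counts were equal to those of bedtools 2.31.1 for 12 of 12 libraries. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.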

Results

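BMAL1 binding was mapped by chromatin immunoprecipitation and sequencing in U2OS, a human osteosarcoma cell line, and in a line of the same cell type named U2OS-CHRONO. BMAL1 is the transcription factor that pairs with CLOCK to activate genes of the circadian clock, and CHRONO, the product of CIART, is known as a repressor of that pair. Cells were treated with 200 nM dexamethasone, which sets the clocks of a culture to a common phase, and collected every 4 h at 6 time points labelled 0, 4, 8, 12, 16 and 20 h, the first lying 4 h before the trough of a BMAL1 promoter luciferase reporter. The 16 samples held 6 BMAL1 libraries of U2OS, 6 of U2OS-CHRONO, 1 library from U2OS-CHRONO precipitated with an antibody to Myc and with no time or treatment label, and 3 input libraries, which were not analysed here. The series design names the target of the Myc library as Myc-CHRONO. There was 1 library per line and time point, so the 6 shared times served as pairs and not as replicates, and the tests measure the spread over these times alone. Read depth was unknown, and peak lists were the measured quantity.

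The first comparison asked how much BMAL1 binding was called in the 2 lines over the cycle. U2OS-CHRONO had more BMAL1 peaks than U2OS at 6 of 6 times. The U2OS lists held 3397, 5287, 337, 1808, 2794 and 6012 peaks at 0, 4, 8, 12, 16 and 20 h, and the U2OS-CHRONO lists held 5612, 8240, 2429, 3919, 9391 and 6873. The mean log2 difference was 1.21 ± 0.96 (SD, n = 6 times), a 2.32-fold geometric mean. The fold lay between 1.14 at 20 h and 7.21 at 8 h. A two-sided exact paired permutation test gave p = 0.031, the smallest that 6 pairs allow, and 0.0625 after Benjamini-Hochberg adjustment over the 4 paired tests, which misses 0.05. Without the pairing the exact permutation p was 0.084, and without 8 h the mean log2 difference was 0.88, with a smallest possible p of 0.0625.

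Both lines had their shortest list at 8 h. Over the 6 times the log2 peak numbers of the lines, the 1 such relation computed, had Pearson's r = 0.87 (exact permutation p = 0.028, n = 6) and Spearman's rho = 0.60 (exact permutation p = 0.24). The relation rested on 8 h. Without the 2 times farthest from the U2OS median, 8 and 20 h, r was 0.66 (exact permutation p = 0.42), and without 8 h alone it was 0.57 (exact permutation p = 0.34). The exact permutation p also missed 0.05 without 0 h (0.050, r = 0.88), 4 h (0.075, r = 0.85) or 12 h (0.12, r = 0.88).

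**Figure D1:**
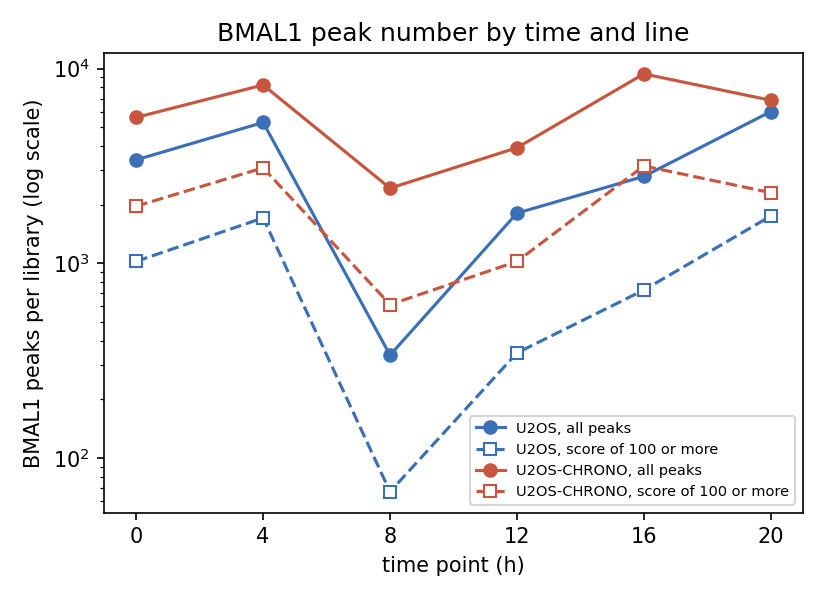
BMAL1 peaks per library (log axis) against time point in hours for U2OS (blue) and U2OS-CHRONO (red), 1 library per point; filled circles are all peaks and open squares are peaks with an authors' score of 100 or more. U2OS-CHRONO lies above U2OS at each of the 6 times, and both lines are lowest at 8 h, at 337 and 2429 peaks.

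The second comparison asked which clock genes BMAL1 occupied. Of the 20 core clock genes, 15 had a peak within 1 kb of either end of the gene in at least 1 BMAL1 library, and 8 had one in all 12: PER1, PER3, CRY1, CRY2, BHLHE40, NR1D1, NR1D2 and DBP. These encode repressors of the clock and, in DBP, an output activator. TEF, a relative of DBP, and PER2, a repressor, were marked in all 12 libraries by peaks inside the gene. TEF had the highest or a near-highest peak of each list: ranks 1 to 3 in U2OS and 2 to 5 in U2OS-CHRONO. The TEF peak at 20 h in U2OS spanned 41379930 to 41382629 on chromosome 22 (hg38). At PER1 the highest peak lay outside the gene, at 8156114 to 8157316 on chromosome 17 at 0 h in U2OS, beyond the gene end at 8152404. BMAL1, CLOCK and NPAS2, of the activating limb, had few gene-end peaks. CLOCK had no peak at a gene end in any library, BMAL1 had one in 1 U2OS-CHRONO library, and NPAS2 had one at 1 U2OS time and 2 U2OS-CHRONO times. RORA, RORB and NFIL3 had no gene-end peak. In the gene or within 5 kb, RORA had a peak at 4 times of each line, NFIL3 at 2 U2OS-CHRONO times and RORB at none. BHLHE41 had a gene-end peak at 4 U2OS and 6 U2OS-CHRONO times, CIART at 5 and 4, HLF at 6 and 4, and TEF at 3 and 6. Whether a CHRONO construct adds reads at CIART in U2OS-CHRONO and in the Myc library is not known.

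U2OS libraries had 12.0 ± 1.67 core clock genes with a gene-end peak (SD, n = 6 times) and U2OS-CHRONO libraries had 12.7 ± 1.75. The mean difference was 0.67 ± 0.82, within the spread over times. The number was higher in U2OS-CHRONO at 3 of 6 times and equal at the others (two-sided exact paired permutation p = 0.25, adjusted p = 0.33). With those ties 0.25 is the smallest p that this test could give, so it cannot show whether the lines differ. At equal list sizes the difference turned to -1.17, again within the spread (exact permutation p = 0.16). There the U2OS-CHRONO list, the longer at each time, was cut to its highest-scoring peaks and the U2OS list was kept whole. The U2OS-CHRONO number could thus only fall or stay. Against all other protein-coding genes, the core clock list was enriched in all 12 BMAL1 libraries by Fisher's exact test, with odds ratios from 16.8 to 229 and adjusted p of 3.3e-08 or less.

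**Figure D2:**
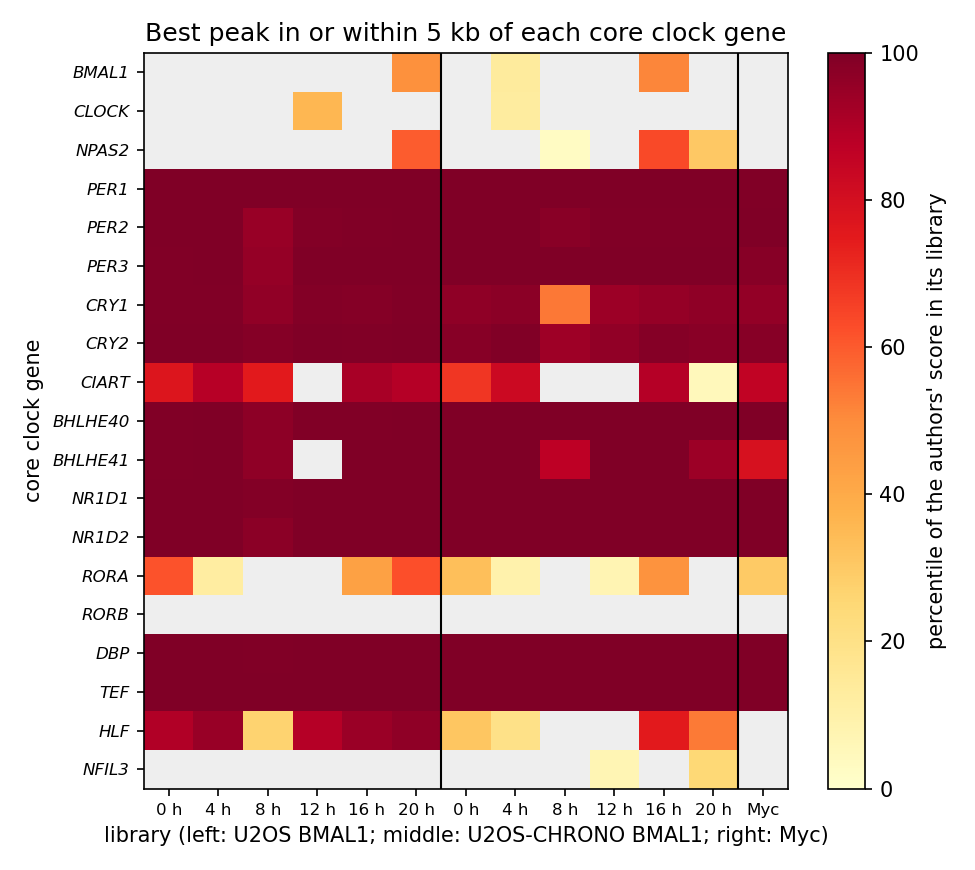
Core clock genes (rows, all but 1 of the list) by library (columns, times in hours, with the Myc library at the right); colour gives the percentile, within its own library, of the authors' score of the best peak in the gene or within 5 kb of it, and grey marks no peak. PER, NR1D, DBP, TEF and BHLHE40 rows are dark in all 12 BMAL1 libraries, whereas BMAL1, CLOCK and NPAS2 have a peak in 3, 2 and 4 of them.

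In all, 72 genes had a gene-end peak in all 12 BMAL1 libraries. Among the 10 with the highest mean score percentile were DBP and CA11, which share 1 peak, NR1D1, NR1D2 and NKIRAS1, which share another, ADIRF and the neighbouring LOC124902474, BHLHE40 and PER3. The DBP and CA11 peak at 16 h in U2OS spanned 48637301 to 48638881 on chromosome 19 and ranked first in its list. Among 18 clock output genes, KLF11 had a peak in 12 libraries, NAMPT, of NAD synthesis, in 11 and KLF9 in 8. That list passed Fisher's exact test at 6 of 6 U2OS and 5 of 6 U2OS-CHRONO times.

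Of 30 MYC target and ribosome biogenesis genes, 21 had a gene-end peak in some BMAL1 library, and the list was enriched at 6 of 6 times in each line, with odds ratios from 6.15 to 19.8 (Fisher's exact test, highest adjusted p = 0.025). CDK4, a cell cycle kinase, and RRP9, an rRNA processing factor, had a peak in 12 libraries, and LDHA, of glycolysis, and NCL, nucleolin, in 11. Of 25 lysosomal genes, 15 had a peak in some library and the list was enriched at 3 of 6 times in each line, with UVRAG in 11 libraries, LAMP1 in 10, ATP6V1H in 9 and CTSA in 8. Of 22 glucocorticoid-induced genes, 11 had a peak, and the list was enriched at 3 U2OS and 4 U2OS-CHRONO times, with PER1 in 12 libraries, CEBPB in 10, and BIRC3 and KLF9 in 8. PER1 and KLF9 stand in this list and in a clock list.

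Clock cofactors passed at 1 U2OS time, with CSNK1E, a kinase of PER proteins, in 10 libraries, SIRT1 in 8, TIMELESS in 6 and EP300 in 4. Cytosolic ribosomal protein genes passed at 1 U2OS-CHRONO time, with RPL27 in 10 libraries, RPL23 in 8, RPL18 in 6 and RPS2 in 5. Cell cycle genes also passed at 1 U2OS-CHRONO time, with AURKA in 6 libraries, MCM7 in 4, and BUB1 and CCND1 in 3. Osteoblast genes and genes of other cell types passed at none. Of the former SPP1 had a peak in 2 libraries and COL1A1 in 1, and of the latter SNAP25 in 11 and HBB in 1. In all, 57 of 130 tests of a list in a library passed. No list had a difference between the lines past the test after adjustment over the 10 lists. The smallest p was shared by the ribosomal protein list, with 1.83 ± 1.72 genes in U2OS and 5.17 ± 1.94 in U2OS-CHRONO, and the cell cycle list, with 0.67 ± 0.82 and 3.33 ± 2.80 (SD, n = 6 times; exact paired permutation p = 0.0625 and adjusted p = 0.31 for each). Each was higher in U2OS-CHRONO at 5 of 6 times.

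**Figure D3:**
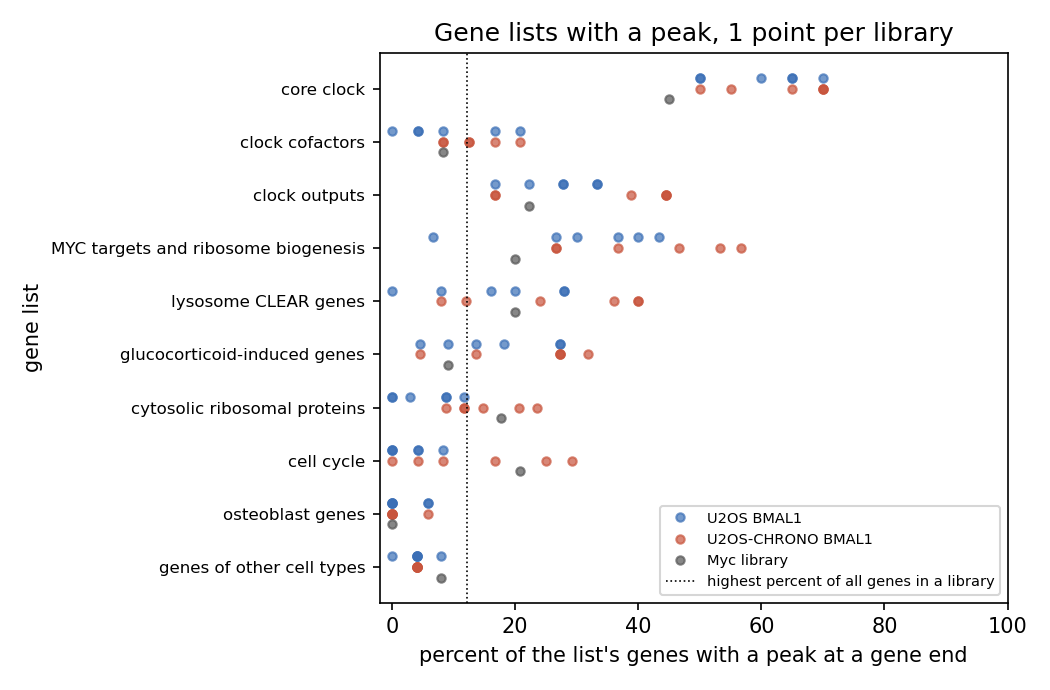
Percent of each list's genes with a peak within 1 kb of a gene end, 1 point per library, for U2OS BMAL1 (blue), U2OS-CHRONO BMAL1 (red) and Myc (grey); the dotted line marks the highest percent of all protein-coding genes in any library, 12.2%. Core clock genes lie between 50% and 70% in the BMAL1 libraries, and osteoblast genes and genes of other cell types lie at the left edge.

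The third comparison asked where the peaks lay and whether the lines resembled each other more at the same time. Gene ends held 23.3% ± 2.41 of the U2OS peaks (SD, n = 6 times) and 23.9% ± 3.91 of the U2OS-CHRONO peaks, a difference within the spread (0.60 ± 3.25 percentage points, exact paired permutation p = 0.66). At equal list sizes the difference was 3.06 ± 2.63 points (exact paired permutation p = 0.0625). Of the U2OS peaks, 47.5% to 64.9% overlapped a U2OS-CHRONO peak of the same time. Of the longer U2OS-CHRONO lists, 7.95% to 41.8% overlapped a U2OS peak. The mean Jaccard index was 0.212 for matched times and 0.193 for unmatched times (one-sided exact permutation p = 0.064). With equal list sizes the means were 0.286 and 0.197 (one-sided exact permutation p = 0.0014, the smallest that all orders of the times allow). Those lists were equal in length only within a time, and lists of unequal length cannot reach a high Jaccard index. Matched times were thus favoured by construction, so that value does not decide the question. Without 16 h the difference passed with all peaks (one-sided exact permutation p = 0.033).

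The fourth comparison asked which regions gained or lost BMAL1 peaks in U2OS-CHRONO. Peaks of the 12 libraries merged into 20968 regions, of which 5652 (27.0%) had a peak in both lines and 11911 in 1 library alone. U2OS-CHRONO had a peak at 4 or more additional times in 1061 regions, and U2OS in 61. In simulated lists, with the lines exchanged at random at each region and time, which removes the difference in list length, 93 and 76 unchanged regions passed these thresholds. That exchange treats regions as independent, so these are not no-change counts for whole libraries. At equal list sizes the real counts were 248 and 109, and other swaps of whole libraries within times gave up to 238 in the larger and 104 in the smaller direction. Among the gained regions 24.7% overlapped a gene end (Wilson 95% interval 22.2 to 27.4%), and among the lost regions 8.20% did (3.55 to 17.8%). The share was 27.5% (26.1 to 29.0%) among other regions with a peak in 4 or more libraries and 19.5% among all regions. A Myc peak overlapped 13.3% of the gained regions (11.4 to 15.5%) and 3.28% of the lost regions (0.904 to 11.2%). It was 20.9% (19.6 to 22.2%) among the other regions with a peak in 4 or more libraries and 6.32% among all regions. A peak at all 6 U2OS-CHRONO times and no U2OS time marked 70 regions, and the opposite 2. Both counts depended on the number of times. With 0, 4, 8, 12, 16 or 20 h left out in turn there were 532, 578, 793, 641, 420 and 623 gained and 16, 11, 60, 32, 29 and 10 lost regions, fewer by construction since 4 of 5 times were then needed. A difference of 3 or more times gave 2542 and 190.

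Per gene, 297 genes had a gene-end peak at 4 or more additional U2OS-CHRONO times and 5 at 4 or more additional U2OS times. These counts use all peaks, and U2OS-CHRONO had the longer list at each time, so they are open to list length. Counts of genes at equal list sizes are not given here. A peak at 6 U2OS-CHRONO times and no U2OS time marked 16 genes. The 10 of these with the highest mean score percentile were PAPSS1, which makes the sulfate donor of the cell, CD2BP2, GNAI2, an inhibitory G protein subunit, PCBD1, TLE3, a transcriptional corepressor, DCAF13 and SLC25A32, which share 1 peak, FOXD1, PEMT, of phosphatidylcholine synthesis, and NDUFB8, of respiratory complex I. The PAPSS1 peak at 16 h spanned 107720027 to 107720584 on chromosome 4, at the gene end at 107720234. In the other direction the difference was 4 times in 5 genes and 3 times in 25, of which the 5 with the highest mean score percentile are named. The 5 genes were YPEL1, SLC2A8, a glucose transporter, ESR2, an estrogen receptor, METTL13 and IRS4, each with a peak at 4 U2OS times and no U2OS-CHRONO time. Of the 25, COQ8A, ANKS3 and DNAAF8, the last 2 sharing 1 peak, had a peak at 3 and 0 times, FLYWCH2 at 4 and 1, and LOC124904414, which shares a peak with CIART, at 5 and 2.

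The fifth comparison asked how far the Myc library shared sites with BMAL1. It held 2487 peaks. All 50 highest by score overlapped a BMAL1 peak of some library, as did 215 of the 231 with a score of 100 or more. Of all its peaks, 1050 (42.2%, Wilson 95% interval 40.3 to 44.2%) overlapped a U2OS BMAL1 peak of any time and 1306 (52.5%, 50.5 to 54.5%) a U2OS-CHRONO one. In 100 random placements on the same chromosomes the highest overlap was 0.563% and 0.684% (permutation p = 0.0099 for each line, the smallest that these placements allow). The highest-scoring gene-end peaks of the Myc library were at NR1D1, DBP and CA11, BHLHE40, NR1D2 and NKIRAS1, ADIRF and LOC124902474, G6PC3, a glucose-6-phosphatase, and ATXN2. The NR1D1 peak spanned 40100445 to 40101080 on chromosome 17. Of the 20 core clock genes, 9 had a Myc peak at a gene end and 13 in the gene or within 5 kb, among them PER1, PER2, CRY1, CRY2 and TEF. Fisher's exact test gave an odds ratio of 14.6 for the core clock list (adjusted p = 2.3e-06), 4.43 for MYC targets (adjusted p = 0.014), 5.06 for clock outputs (adjusted p = 0.033), 4.43 for lysosomal genes (adjusted p = 0.025), 4.66 for cell cycle genes (adjusted p = 0.023) and 3.80 for ribosomal protein genes (adjusted p = 0.024). The other 4 lists did not pass in this library.

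At each of 6 times a larger share of the Myc peaks overlapped a BMAL1 peak of U2OS-CHRONO than of U2OS. The means were 35.8% ± 8.50 and 22.8% ± 10.4 (SD, n = 6 times), a difference of 13.0 ± 5.27 percentage points (two-sided exact paired permutation p = 0.031, adjusted p = 0.0625). At equal list sizes the difference was 5.42 points. A gene with a Myc peak at its end had a BMAL1 gene-end peak at 2 or more times in 35.0% of cases in U2OS, against 4.02% of other genes (Fisher's exact test, odds ratio 12.8, 95% interval 11.1 to 14.9, p = 1.2e-209), and in 50.9% against 8.89% in U2OS-CHRONO (odds ratio 10.6, 9.32 to 12.1, Fisher p = 8.0e-250). Genes are not replicates, so these values describe these libraries.

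**Figure D4:**
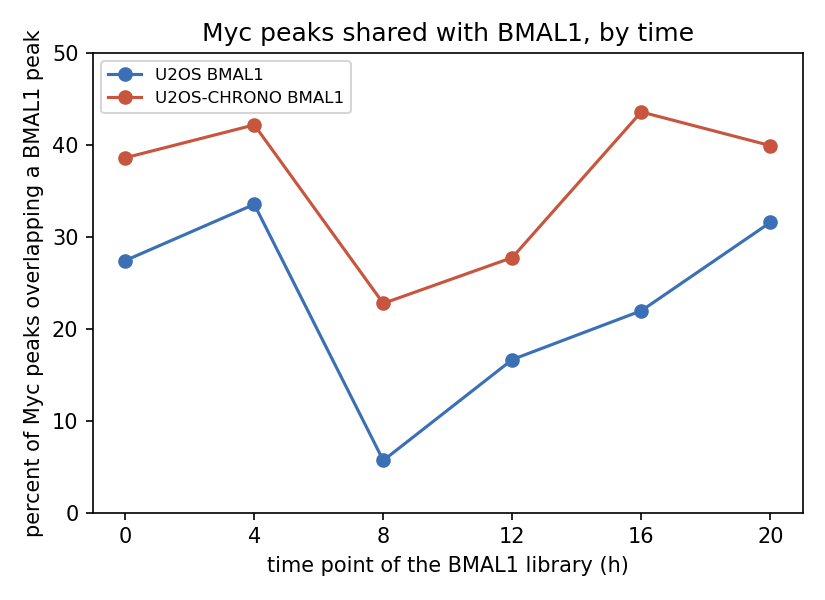
Percent of the 2487 Myc peaks that overlapped a BMAL1 peak by at least 1 bp, against the time point in hours of the BMAL1 library, for U2OS (blue) and U2OS-CHRONO (red), 1 library per point. U2OS-CHRONO lies above U2OS at each of the 6 times, from 22.8% at 8 h to 43.6% at 16 h.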

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

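The tests of explanations in this part were chosen after the results were seen, except the swaps for lost regions. Among 12 sets of 6 libraries tested for 1 library far from the others, 1 stood apart: the U2OS list of 8 h, whose median peak width was 743 bp, with a gap to the next library of 0.70 of the whole range. Chance gives about 1 in 20 sets. That list was also the shortest, with 337 peaks, and no explanation was tested.

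The larger number of regions gained than lost in U2OS-CHRONO was weighed against list length, chromosome copies and chance. Of the 32 ways to swap the lines within times, 1, the real one, gave 1061 or more regions in its larger direction (highest other 630), and 2 gave 61 or more in the smaller direction (highest other 62), but U2OS-CHRONO had the longer list at 6 of 6 times, which favours the real labelling in the first count and disfavours it in the second, so these swaps decide nothing. Of 100 splits of the 12 libraries, which ignore the pairing by time and are open to list length too, 1 gave 1061 or more, with 994 as the highest other. At equal list sizes 1 of 32 swaps, which keep the pairing by time, reached the 248 gained regions, with 238 as the highest other. That is the fewest swaps possible, and the nearest other swap lay close. Of the 100 splits, which ignore the pairing, 15 reached 248, with up to 585. Those lists were equal in length only within a time, so splits across times stay open to list length and decide nothing here. Chance is not excluded for the gained regions, since the nearest other swap lay close. For the 109 lost regions at equal list sizes 1 of 32 swaps gave as many, with 104 as the highest other, again close. Of the splits, 1 of 100 did (highest other 40), with the same limit. With all peaks, extra copies of whole chromosomes are not the whole cause. The share of regions gained ran from 3.74% (Wilson 95% interval 2.48 to 5.59%) on chromosome 22 to 6.82% on chromosome 19, against 0.291% of all regions lost. Longer lists can raise that share on every chromosome, and it was not computed at equal list sizes. The part of chromosome copies in the excess at equal sizes is therefore open. Longer lists from deeper or better enriched libraries cannot be told apart from more binding. The ratio of gained to lost regions was 17.4 with all peaks and 2.28 at equal sizes, other swaps reached 6, and depth is not known.

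Gene ends that any library picks up may add to the sharing of sites by the Myc library but are not its whole cause, since 51.2% of the Myc peaks away from gene ends overlapped a BMAL1 peak, against 63.4% at gene ends; open chromatin away from genes was not tested. Endogenous MYC, which binds E-boxes as BMAL1 does, could account for part of the peaks: the MYC target list had an odds ratio of 4.43, below the 14.6 of the core clock list, and this leaves it open, because that list was enriched in all 12 BMAL1 libraries too and no Myc library from U2OS without the tagged protein was analysed here. For the higher share in U2OS-CHRONO than in U2OS, the number of peaks alone is not the whole cause. The difference was above 0 at 6 of 6 times at equal list sizes, at 5.42 instead of 13.0 points. Those lists set the highest-scoring U2OS-CHRONO peaks against the whole U2OS lists, which does not equalise depth or enrichment. Deeper or better enriched U2OS-CHRONO libraries therefore cannot be told apart here. Binding of the tagged protein beside BMAL1 stays open as an untested biological explanation.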

How the results depend on the processing

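The window of the gene with 5 kb to each side, and for the list enrichment the score of 100, equal list sizes, chromosomes and left-out times, were chosen after seeing the data. Of 139 values, 100 kept their direction and side of the threshold, or a count within 1.5 times, among them all of those of the Myc overlap over any time and of the Myc and BMAL1 genes, whose sizes moved nonetheless: at a score of 100 or more the overlap was 72.3% in U2OS and 80.5% in U2OS-CHRONO and the odds ratios 55.6 and 45.9, and with the gene plus 5 kb window the odds ratios were 6.78 and 6.89. The E-box share was not run, for lack of a genome sequence. Leaving out a time raises the smallest paired p to 0.0625, so calls ended there by construction: the log2 peak number difference was 0.88 to 1.42 and the Myc share difference 11.3 to 13.9 points. Without the pairing by time (no replicate block) the peak number difference was 1.21 and its unadjusted exact p missed 0.05, which that of the paired test met; no other unadjusted call changed. The time profile r ran from 0.57 (without 8 h) to 0.97 with 1 time left out. The gene-end share difference turned to -5.25 points at a score of 100 or more and to -0.14 without 0 h, up to 1.52 with 1 time left out, and was 3.06 at equal list sizes; it passed no test. The core clock difference turned to -0.83 at a score of 100 or more and to -1.17 at equal list sizes, with no test passed. The same-time Jaccard difference passed at equal list sizes (0.0889) and without 16 h (0.0293), and was lowest without 8 h (0.0131). The pass at equal list sizes was favoured by construction, since lengths were equal within a time alone. Gained regions numbered 499 at a score of 100 or more, 248 at equal list sizes, 2542 with a difference of 3 times and 420 to 793 with 1 time left out; lost regions numbered 25, 109, 190 and 10 to 60. Fewer peaks or times leave fewer regions able to pass, and a difference of 3 times lets more pass. Equal list sizes shortened the U2OS-CHRONO lists alone, since these were the longer at each time. That favours fewer gained and more lost regions by construction. The cause of the other changes was not tested. Unknown depth limits any comparison of list lengths.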

Other observations

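The ranking itself was chosen after the data were seen, the tests of it were written before their own results, and the spread used to judge the test of copies was set after its value was seen. A set of 167 regions had a peak in all 12 BMAL1 libraries; 118 of them had a Myc peak and 71 overlapped a gene end. Ranked by score among these same 167 regions, 32 were lower in U2OS-CHRONO at 6 of 6 times and 32 higher. Among lowered regions with a gene within 5 kb, chosen after their values were seen, were those at TRAPPC6A and BLOC1S3 (mean rank 16.3 ± 3.27 in U2OS and 123 ± 17.1 in U2OS-CHRONO, SD, n = 6 times), CDC25B (62.8 ± 14.0 and 161 ± 5.31), BCAT1 (39.2 ± 11.8 and 133 ± 21.1), CRY1 (24.8 ± 9.79 and 116 ± 24.2) and CRY2 (9.33 ± 6.28 and 70.5 ± 13.0). Of 14 regions at core clock genes 5 were lower at all 6 times, at CRY1, CRY2, PER2 and 2 at PER1, and 3 were higher, at NR1D1, BHLHE40 and DBP. The other DBP region was at 2.33 in both lines. The other NR1D1 region, at 13.8 ± 8.33 in U2OS and 11.2 ± 3.71 in U2OS-CHRONO, was lower at 3 of 6 times. The PER3 region was at 11.5 ± 3.78 and 11.2 ± 2.64. The regions at NR1D2, TEF and BHLHE41 were lower at 4, 5 and 3 of 6 times. Among the 5 lowered regions the sizes differed. The PER2 region was at 14.0 ± 4.52 and 27.5 ± 11.9. The PER1 regions were at 3.00 ± 1.10 and 6.67 ± 3.08, and at 56.5 ± 15.3 and 131 ± 12.7. Raised regions included those near ABHD2 (120 ± 21.6 and 37.5 ± 3.73), CLUAP1 (138 ± 6.79 and 59.7 ± 10.2) and SERF2 (138 ± 34.7 and 69.3 ± 18.2).

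A candidate explanation is that U2OS-CHRONO has less BMAL1 at CRY1 and CRY2 relative to other shared sites; a common direction of clock repressor genes was not tested, and PER3, NR1D1 and BHLHE40 were not lower on average. Of the 32 within-time swaps of the lines, 1, the real one, gave 64 or more regions with 1 direction at all times, and the highest other gave 12. That number of regions was thus far above those of the other swaps. It is also the fewest swaps possible, for a ranking chosen after the data were seen. A chance difference between the single sets of libraries of the lines would also give 1 direction at all times and was not tested. The swaps do not test CRY1 and CRY2 themselves. Division of a broad peak into several is not the whole cause at CRY1 and CRY2: with the scores of a region added up both were lower at 6 of 6 times, by at least 48.8 ranks on average. Fewer copies of the surrounding chromosome cannot be told apart, because only 5 shared regions lie within 10 Mb. Of these, 4 lie near CRY1 (median rank change -58.25, SD 95.8) and 1 near CRY2 (change 0). The median rank change of all 5 was -20.2 (SD 87.8), upwards. It was 145 downwards for CRY1 and CRY2, among the 614 regions common to the 10 libraries without 8 h. A rank gives no amount of binding, and a change of the U2OS-CHRONO line unrelated to CHRONO was not tested.

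A second CRY2 region, inside the gene at 45859569 to 45860312 on chromosome 11, had a peak at 6 U2OS times and 1 U2OS-CHRONO time. At CIART a peak over the lower end of the gene was called at 4 U2OS times and 1 U2OS-CHRONO time, and peaks inside the gene at 2 and 4 times; the Myc library had 2 inside peaks, at 150283265 to 150283612 and 150286430 to 150286988 on chromosome 1. Whether reads of a CHRONO construct contribute to the inside peaks of U2OS-CHRONO and Myc was not tested, and peaks inside the gene were also called in U2OS, which leaves open how much of the CIART counts of those libraries lies at the native gene.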
